A study of Homo sapiens with 6 samples.

How the data were processed

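Polyadenylated RNA of 6 libraries of ox-LDL-treated THP-1 macrophages, 3 controls and 3 with MCT4 deficiency (siMCT4), was sequenced as paired ends after a strand-marking dUTP preparation, per the labels' protocols. The submitters' processing notes name cutadapt 1.9, a read trimmer, and HISAT2 2.2.1, a splice-aware aligner, with the genome build GRCh38. The counting tool, its annotation and its strand setting are not given in the sources used here. Per the file headers, the deposited table holds raw counts and FPKM (fragments per kilobase of gene and 1000000 fragments) for each of 35009 genes and 6 libraries, 12 columns of which 0 went unused. The counts are whole numbers, not normalized, and the deposited FPKM equals the count divided by a length per gene and a factor per library. Even counts made up 58.7% to 60.9% of counts from 2 to 41, so both mates of a pair appear to have been counted, and 2 counts then stand for 1 fragment.

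The test planned before the data were examined was limma on log2(FPKM + 1), with edgeR in its place should the table hold raw counts. Since it does, edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling was run on the counts as deposited, two-sided, with group as the sole factor and Benjamini-Hochberg adjustment. Genes passed filterByExpr with a smallest count of 10 and a smallest total of 15, which left 19944. A gene was called at an adjusted p under 0.05. Standard errors are the log2 change divided by the square root of the quasi-likelihood F. CPM values are counts per 1000000 counts of the library with TMM scaling, and their SD is over the 3 libraries of a group. SLC16A3 was also tested with an exact two-sided permutation test over 20 assignments of the 6 values.

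Total counts ran from 61880619 to 69181938 per library. Genes with any count numbered 26426 ± 189 in controls and 27317 ± 130 in siMCT4 (SD, n = 3), and the 10 most abundant genes took 8.87 ± 0.0658% and 7.36 ± 0.177% of counts. Where a group had 0 counts, the fold is a bound against 3 counts over the 3 libraries of the group together; such bounds cover counting error only, and are smaller where 2 counts stand for 1 fragment. The common biological coefficient of variation was 0.219.

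The 34 gene lists were fixed from general knowledge of macrophages, ox-LDL, lactate metabolism, other cell types and RNA quality. Each symbol was looked up as written, and the copy with the highest mean FPKM was used where a symbol occurs more than once. Lists with at least 5 tested members (33) were tested with camera (limma 3.58.1) with a preset correlation of 0.01, then with an estimated correlation, with ranks and with fry. The functional terms that the deposited table attaches to genes were tested in the same way where 15 to 300 of their genes were tested.

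The genes named in the text follow a rule. It takes SLC16A3, the 10 largest rises and 10 largest falls in log2(FPKM + 1) among called genes with a symbol, non-overlapping groups and a mean FPKM of at least 1 in the higher group, up to 4 members with the smallest adjusted p of each called list and up to 2 called members of each other list, and 18 genes of cholesterol handling, inflammation, repair and lactate transport whatever their values. Outside this rule, SERPINB3, MARCO, CCL18, CD163, CD86, CCL3, IL1A, CXCL8, ISG15, IRF7, IFI6, PHGDH, MMP9 and CDKN1A were named after their values were seen. So were THBS1 and the untested COL1A2 and AKR1B10. A few genes that the rule takes are not reported here.

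The edgeR step, DESeq2 1.42.0, limma and the GC corrections were tested on simulated counts drawn from the real means and library sizes, 3 against 3, with 200 changed genes. In the real data 41.4% of tested genes were called, so the shares recovered in the simulation do not carry over to the real comparison. In the simulated siMCT4 against control comparison over 19944 genes, edgeR recovered 23.9% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 95.5% of those changed 4-fold, and called 14 unchanged genes. DESeq2, run on 19936 genes, recovered 58.2%, 82.1% and 95.5% and called 60 unchanged genes. Limma on log2(FPKM + 1) recovered 10.4%, 38.8% and 84.8% with 8 unchanged genes called, and edgeR with a replicate block 14.9%, 46.3% and 90.9% with 17. A simulated GC-dependent loss gave 427 unchanged GC-rich genes a median log2 change of -0.558, which the GC correction brought to 0.0201. Camera gave a planted list of 30 raised genes p = 3.07e-38 (0.000124 with an estimated correlation) and gave 1 of 200 random lists p under 0.05. The simulated genes varied independently of each other, so this cannot show how often camera calls lists whose genes vary together. In the real data the ribosomal protein list had an estimated correlation of 0.723.

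Alternatives planned before the data were examined were limma on log2(FPKM + 1) and its variants (median-ratio, TPM and quantile scaling; pseudocounts of 0.1 and 0.5; FPKM filters of 0.1, none and a mean of 5; no variance trend, robust fitting and array weights; the replicate number as a block), DESeq2, edgeR with median-ratio scaling, without a filter and with the block, stricter thresholds, other list tests and leaving out each library. Chosen after seeing the data were loess corrections (span 0.3) for GC content and for GC content with length, genes with a GC content under 55% alone, siMCT4 library 3 alone against the controls, halved counts, robust edgeR and the lactate list without SLC16A3. GC content and length come from GENCODE release 29 transcripts and were found for 19298 tested genes (96.8%), as was the locus of SLC16A3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

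Several values are uncertain because reads can be shared between near-identical genes: SERPINB3 and SERPINB4, CCL3 and CCL4 with their copies, HLA and histone genes, ribosomal protein genes with their pseudogenes, and mitochondrial genes with nuclear copies. The same holds for overlapping and antisense genes, since the strand setting of the counting is unknown here. The labels do not say whether the controls received a non-targeting siRNA. Ox-LDL dose, treatment time and a group without ox-LDL were not analysed here. Protein, lactate and histone lactylation measurements were not used here.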

Results

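Polyadenylated RNA was sequenced from macrophages derived from THP-1, a human monocytic leukaemia cell line, after exposure to oxidised low-density lipoprotein (ox-LDL), the modified lipoprotein that macrophages of the artery wall take up when they become foam cells. The 6 libraries form 2 groups of 3: ox-LDL controls and ox-LDL cells deficient in MCT4, labelled siMCT4. MCT4, encoded by SLC16A3, is a monocarboxylate transporter that carries lactate and protons out of glycolytic cells. The deposited table gives a read count and an FPKM value per gene and library. Total counts were 69181938, 65880212 and 65010219 in control libraries 1, 2 and 3, and 61880619, 67486614 and 69103124 in siMCT4 libraries 1, 2 and 3. The comparison is of siMCT4 with control libraries of ox-LDL-treated macrophages. Genes of reparative activation, lactate handling and histone acylation are among those the study's title brings forward. Whether the controls received a non-targeting siRNA is not given in the labels. For every change below, an effect of MCT4 loss therefore cannot be told apart from one of the siRNA itself. The labels do not say that the 3 libraries of a group are separate cultures, so all p-values measure only the spread between these samples.

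The targeted gene, SLC16A3 (ENSG00000141526.16; GRCh38 chromosome 17, 82228397 to 82261129, + strand, annotated as protein_coding), had 7708, 6428 and 6848 counts in control libraries 1, 2 and 3. It had 691, 768 and 949 counts in the siMCT4 libraries. In CPM (counts per 1000000 counts of the library, with TMM scaling), expression was 108 ± 7.21 (SD, n = 3) in controls and 11.8 ± 1.42 (SD, n = 3) in siMCT4. SLC16A3 fell by 3.20 on the log2 scale (SE 0.102; adjusted p = 1.12e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which gives every gene-level adjusted p below). The 3 values of a group did not overlap those of the other; the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. SLC16A1, which encodes the related transporter MCT1, had a log2 change of 0.12 (adjusted p = 0.108), but passed as higher in 14 of 29 alternative settings. Among these were TPM (0.32, adjusted p = 0.0035), siMCT4 library 3 alone against the controls (0.23, adjusted p = 0.0172) and the fit without siMCT4 replicate 2 (adjusted p = 0.0377), the range for SLC16A1 over all alternatives being 0.00222 to 0.474.

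MCT4-deficient macrophages had higher expression of interferon-response genes and of several chemokines, together with lower expression of integrated stress response, ribosomal protein and cell cycle genes. The last 2 of these lists were not called against other genes with an estimated correlation (adjusted p = 0.306 for ribosomal protein and 0.235 for cell cycle genes). Of 34 tested interferon-response genes 31 rose, with a median log2 change of 2.09, and the antiviral gene RSAD2 rose from 1.93 ± 0.367 to 477 ± 20.5 CPM (mean ± SD, n = 3 libraries per group here and below). CCL22, a chemokine of alternatively activated macrophages, rose from 74.0 ± 1.18 to 4816 ± 185 CPM, and the anti-inflammatory cytokine IL10 from 0.976 ± 0.242 to 22.6 ± 1.70 CPM. The inflammatory cytokine IL1B fell from 349 ± 9.18 to 28.2 ± 3.49 CPM, the proliferation marker MKI67 from 111 ± 6.10 to 11.4 ± 2.91 CPM, and all 36 tested ribosomal protein genes fell, with a median log2 change of -0.85. The cholesterol exporter ABCA1 stood at 1078 ± 20.2 CPM in controls and 1031 ± 11.02 CPM in siMCT4, a difference that did not pass the test (log2 change -0.06, adjusted p = 0.194). ABCA1 passed as lower after GC and length correction (-0.12, adjusted p = 0.0192) and with genes under 55% GC (-0.13, adjusted p = 0.0184). It passed as higher on TPM (0.14, adjusted p = 0.0213) and under quantile normalisation (0.13, adjusted p = 0.0207), and had the opposite sign in 12 of 29 alternative settings. Over all of them the adjusted p of ABCA1 ran from 0.0184 to 0.627.

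**Figure D1:**
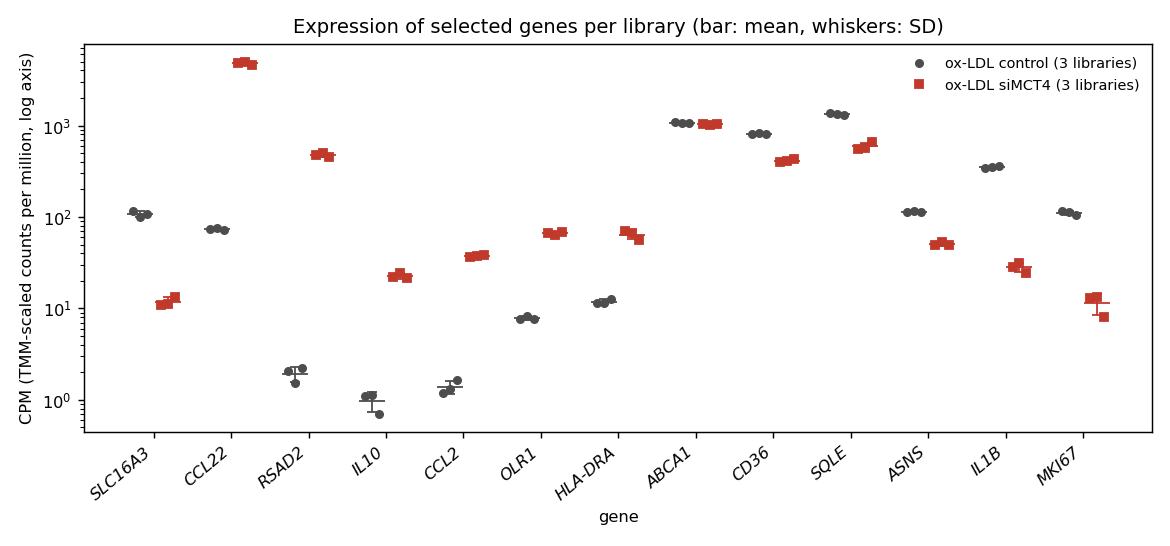
Expression of 13 genes in CPM (log axis) in the 3 control and 3 siMCT4 libraries; points are libraries and bars the group mean ± SD. SLC16A3, IL1B and MKI67 lie lower and CCL22, RSAD2, IL10 and OLR1 higher in every siMCT4 library, while ABCA1 lies near 1078 CPM in controls and 1031 CPM in siMCT4.

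Of 19944 genes tested, 4116 were higher and 4144 lower in siMCT4 at an adjusted p under 0.05, together 41.4% of the tested genes. With a change of at least 2-fold required as well, 1268 were higher and 1339 lower. The 3 values of each group did not overlap for 10970 genes (55%), where chance gives 10%. The balance of directions depended on scaling: on FPKM rescaled to TPM 4961 genes were higher and 2350 lower (67.9% of calls higher, against 49.8% in the edgeR fit), with the median of all genes shifted by 0.193 on the log2 scale. The siMCT4 libraries were not alike in GC-rich genes. This was seen in the 402 genes with a log2 CPM above 2 and a GC content of 64% or more. Their median log2 ratio to the control mean was -0.97 and -1.09 in siMCT4 libraries 1 and 2 and -0.22 in library 3.

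**Figure D2:**
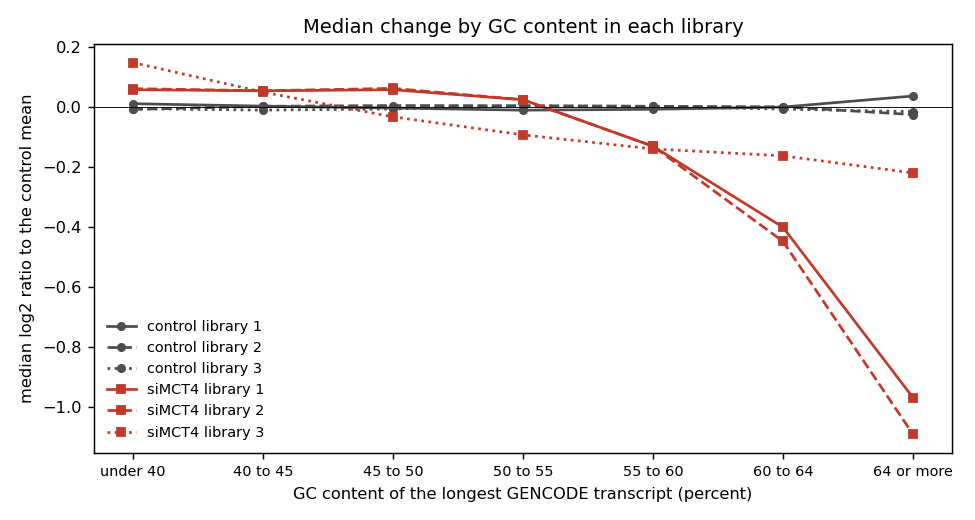
Median log2 ratio of each library to the mean of the 3 controls (y axis), 1 line per library. Genes with a log2 CPM above 2 are binned by transcript GC content in percent (x axis). At 64% or more, siMCT4 libraries 1 and 2 lie at -0.97 and -1.09, library 3 at -0.22, and the controls near 0.

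Ranked by change in log2(FPKM + 1), among called genes with non-overlapping groups and a mean FPKM of at least 1 in the higher group, the 10 largest rises included chemokines and interferon-induced genes; the log2 changes printed are those of edgeR. CCL8 (log2 change 8.33), CCL4 (6.28) and CCL7 (5.78), which attract monocytes and T cells, rose beside CCL22 (6.02, SE 0.0511, adjusted p = 5.91e-09). RSAD2 rose by 7.95 (SE 0.138, adjusted p = 1.32e-07), IFIT1, an inhibitor of viral translation, by 6.26 (adjusted p = 7.85e-08) and IFI27 by 4.80. SERPINB4, a serpin protease inhibitor, had 0, 4 and 4 counts in controls and 6811, 7270 and 7695 in siMCT4. Its neighbour SERPINB3, a near-identical copy with which reads can be shared, had 0 counts in controls and 688, 674 and 740 in siMCT4, at least 666-fold higher. The macrophage elastase MMP12 (7.26) and the secreted ribonuclease RNASE1 (4.56) were also among these 10. Without control replicate 3 the change of MMP12 was 7.87.

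Among the 10 largest falls by the same ranking were the inflammatory mediators IL1B (log2 change -3.63, SE 0.0950, adjusted p = 5.14e-07) and CCL20 (-3.77), the lipolysis inhibitor G0S2 (-3.72), and the mitotic genes CDC20 (-3.48), MKI67 (-3.28) and TOP2A (-3.14). G0S2 was uneven within siMCT4, with 7279, 7301 and 7247 counts in controls and 210, 290 and 1288 in siMCT4 libraries 1, 2 and 3, and fell by 4.89 without siMCT4 replicate 3. TRIB3, a pseudokinase induced by amino acid shortage, fell by 2.75, the pseudogene SIGLEC17P by 3.83 and the haemostatic glycoprotein gene VWF by 2.83. Of tested genes with 0 counts throughout a group, the scavenger receptor MARCO had 395 counts over the controls and 0 over siMCT4, at least 139-fold lower (adjusted p = 0.000162). The chemokine CCL18 had 0 counts over the controls and 895 over siMCT4, at least 283-fold higher (adjusted p = 4.31e-05). Such bounds set a group at 0 to 3 counts over its 3 libraries together. If 2 counts stand for 1 fragment, a floor of 3 fragments is 6 counts, and the bounds become at least 333-fold for SERPINB3, 69.3-fold for MARCO and 142-fold for CCL18.

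Gene lists were compared by camera, which tests a list against all other tested genes; its adjusted p used a preset correlation of 0.01 between genes, and 20 of the 33 lists tested were called. With an estimated correlation, 7 calls held: lactate handling, sterol synthesis, reparative activation, NF-kB, interferon, integrated stress response and monocyte-to-macrophage differentiation. The lactate call did not hold in that test without SLC16A3, the siRNA's own target. The directional test of fry, which does not compare a list with other genes, called 28 lists. Beside camera's calls, it called as lower TCA cycle, PPAR targets, apoptotic clearance, inflammasome, unfolded protein response and NRF2 targets. The fry adjusted p of these lists ran from 0.00362 to 0.0441. It called p53 targets and immediate early genes as higher (fry adjusted p = 0.0053 and 0.0302). For lists, called and not called below refer to camera. Medians below are of log2 changes over the tested members of a list.

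**Figure D3:**
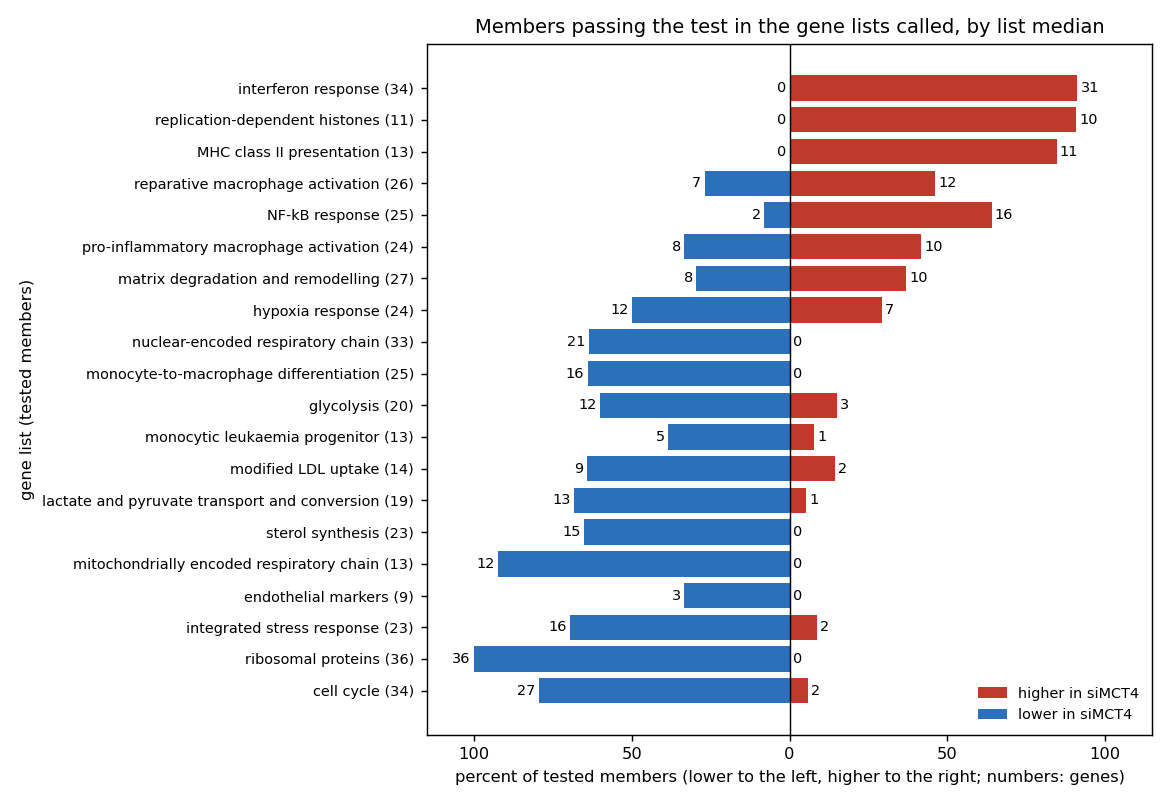
Percent of tested members higher (right) and lower (left) in siMCT4 at an adjusted p under 0.05 for the 20 lists called by camera, ordered by median log2 change, with numbers of genes beside the bars. The interferon list has 31 of 34 members higher and the ribosomal protein list 36 of 36 lower.

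Interferon-response genes were the list with the smallest p: 31 of 34 rose, 0 fell and 3 did not pass, and 32 rose when adjusted over the list alone (median 2.09, adjusted p = 6.2e-110, or adjusted p = 0.000427 with an estimated correlation). Beside RSAD2 and IFIT1, IFIT3 (log2 change 3.66) and IFI44L (4.84) rose. The medians of siMCT4 libraries 1, 2 and 3 were 2.16, 2.12 and 2.26. The 3 members that did not pass were ISG15, a ubiquitin-like modifier (1.34, adjusted p = 0.0746), IRF7, a transcription factor of interferon genes (-0.83, adjusted p = 0.217), and IFI6 (-0.20, adjusted p = 0.734). Without siMCT4 replicate 3, ISG15 stood at 0.46 (adjusted p = 0.1), while IRF7 (-1.70, adjusted p = 7.04e-05) and IFI6 (-0.86, adjusted p = 0.00875) passed as lower. ISG15 passed as higher in 5 of 28 alternative settings, among them without siMCT4 replicate 2 (adjusted p = 0.028) and after GC correction (adjusted p = 0.0103). IFI6 was positive in 5 of 28, with 0.06, 0.06 and 0.07 without control replicate 1 or siMCT4 replicate 1 or 2, and IRF7 in 1, siMCT4 library 3 alone (0.13, adjusted p = 0.493). Over all alternatives the adjusted p of ISG15, IRF7 and IFI6 ran from 0.000189 to 0.232, 7.04e-05 to 0.585 and 0.00875 to 0.938.

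Of the reparative activation list, 12 of 26 members rose, 7 fell and 7 did not pass (13 higher and 7 lower adjusted over the list alone, median 0.85, adjusted p = 1.76e-13, or adjusted p = 0.0169 with an estimated correlation). Beside CCL22 and IL10 (log2 change 4.53, adjusted p = 4.65e-06), the crosslinking enzyme TGM2 rose from 1137 ± 37.1 to 6232 ± 55.2 CPM, the lectin CD209 by 2.27 and the interleukin 1 receptor antagonist IL1RN from 1478 ± 0.0626 to 3031 ± 70.6 CPM. Members that went against the list's name were the haemoglobin scavenger receptor CD163 (-1.57, adjusted p = 3.10e-05), the growth factor VEGFA (-0.26, adjusted p = 0.00198, but -0.10 and adjusted p = 0.104 with GC and length corrected and -0.06 and adjusted p = 0.247 on TPM, with 0.000234 to 0.247 over all alternatives) and TGFB1 (-0.73, adjusted p = 0.00753). TGFB1 has a GC content of 63.4% and its ratios in siMCT4 libraries 1, 2 and 3 were -0.96, -0.85 and -0.42; with a GC correction its log2 change was -0.25 (adjusted p = 0.0684, with 2.39e-06 to 0.0684 over all alternatives). The mannose receptor MRC1 was barely expressed and had a log2 change of 0.81 (adjusted p = 0.536). The list lost its call in 9 of 31 alternative settings, among them log2(FPKM + 1) (adjusted p = 0.0518), TPM (adjusted p = 0.0934) and camera on ranks (adjusted p = 0.0551). It kept its call with median-ratio scaling of FPKM and under quantile normalisation (adjusted p = 0.0113), with 3.71e-14 to 0.615 over camera's alternatives.

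The pro-inflammatory list was split, with 10 of 24 members higher, 8 lower and 6 not passing (12 and 8 adjusted over the list alone, median 0.29, adjusted p = 0.000552, or adjusted p = 0.0612 with an estimated correlation). CCR7, a homing receptor of lymph nodes (log2 change 4.34), the costimulatory ligand CD86 (3.89), and the chemokines CCL2 (4.76, from 1.37 to 37.3 CPM), CCL5 (2.39) and CCL3 (2.64) rose. The cytokines IL1B and IL1A (-1.96), the neutrophil chemokine CXCL8 (-0.94) and CCL20 fell, contrary to the list's name. TNF had a log2 change of -2.01 (adjusted p = 0.128), and IL6, with 0 counts in controls and 4, 16 and 0 in siMCT4, was too low to test. The list was not called with siMCT4 library 3 alone against the controls (adjusted p = 0.107, with 0.000106 to 0.725 over camera's alternatives).

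NF-kB response genes rose in 16 of 25 cases, fell in 2 and did not pass in 7 (16 and 2 adjusted over the list alone, median 0.58, adjusted p = 1.48e-09, or adjusted p = 0.0226 with an estimated correlation). They included the ubiquitin ligase BIRC3 (log2 change 3.88), the dendritic cell antigen CD83 (1.30), and the feedback inhibitors TNIP1 (1.23) and NFKBIA (1.54). MHC class II presentation rose in 11 of 13 genes, with 0 lower and 2 not passing (11 and 0 adjusted over the list alone, median 0.98, adjusted p = 1.92e-07). Its call was lost at adjusted p = 0.178 with an estimated correlation. HLA-DRA rose by 2.44, HLA-DPA1 by 2.28, the invariant chain CD74 by 1.43 and the invariant chain protease CTSS by 0.47. The inflammasome and pyroptosis list was not called (3 of 18 higher, 8 lower, 7 not passing, or 3 and 8 adjusted over the list alone, median -0.34, and 0.03 on TPM; adjusted p = 0.273). In it the thioredoxin inhibitor TXNIP rose by 1.29 and the pore-forming GSDME fell by 1.22.

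Lactate and pyruvate genes fell: 1 of 19 was higher, 13 lower and 5 did not pass (1 and 14 adjusted over the list alone, median -0.50, adjusted p = 2.71e-05, or adjusted p = 0.0468 with an estimated correlation). SLC16A3 itself is a member, and without it the list had 1 of 18 higher and 12 lower (median -0.47, adjusted p = 0.0019), but was not called with an estimated correlation (adjusted p = 0.0831, with 6.33e-07 to 0.0831 over camera's alternatives). Pyruvate carboxylase (PC) fell by 1.92, and the pyruvate dehydrogenase kinases PDK1 and PDK2 fell by 1.01 and 0.68. LDHA, the subunit of lactate dehydrogenase that favours lactate formation, had a log2 change of -0.35 (adjusted p = 0.0355) with -0.21, -0.24 and -0.64 in siMCT4 libraries 1, 2 and 3. LDHA lost its call in 17 of 29 alternative settings, among them without control replicate 1, 2 or 3 (adjusted p = 0.0901, 0.0994 and 0.094) or siMCT4 replicate 2 (adjusted p = 0.0564), with 0.000209 to 0.253 over all of them. BSG, the chaperone of MCT1 and MCT4, fell by 0.50 (adjusted p = 0.00288), and by 0.16 after GC correction.

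In glycolysis 3 of 20 genes were higher, 12 lower and 5 did not pass (3 and 12 adjusted over the list alone, median -0.39, adjusted p = 0.00318). Its call was lost at adjusted p = 0.335 with an estimated correlation. The glucose transporter SLC2A3 fell by 1.76 and PGAM1 by 0.83, while PFKP and the regulatory enzyme PFKFB4 rose by 0.43 and 1.57. The TCA cycle list was not called (3 of 21 higher, 9 lower, 9 not passing, or 3 and 9 adjusted over the list alone, median -0.19, but 0.02 on TPM; adjusted p = 0.288). IDH1, the cytosolic isocitrate dehydrogenase, rose by 1.13. With siMCT4 library 3 alone the TCA list passed as lower (adjusted p = 0.0204, with 0.0204 to 0.755 over camera's alternatives).

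Nuclear-encoded respiratory chain genes were 0 higher, 21 lower and 12 not passing of 33 (0 and 24 adjusted over the list alone, median -0.35, adjusted p = 0.000525, or adjusted p = 0.474 with an estimated correlation). Examples are COX5A (log2 change -0.84), NDUFS3 (-0.67), UQCRC2 (-0.54) and ATP5F1B (-0.39). Mitochondrially encoded genes were 0 higher, 12 lower and 1 not passing of 13 (0 and 13 adjusted over the list alone, median -0.54, adjusted p = 1.42e-06, or adjusted p = 0.229 with an estimated correlation). The mitochondrially encoded list was also not called under quantile normalisation of FPKM (adjusted p = 0.655, with 8.96e-11 to 0.655 over camera's alternatives), and its median was -0.34 with GC and length corrected. MT-CO3 fell by 0.71, MT-ND6 and MT-ATP6 by 0.70 and MT-ATP8 by 0.61; under quantile normalisation of FPKM MT-ATP6 rose by 0.08 and MT-ATP8 lost its call (adjusted p = 0.117, with 2.07e-16 to 0.117 over all alternatives). Mitochondrially encoded genes took 4.65 ± 0.177% of counts in controls and 3.27 ± 0.0789% in siMCT4. The mitochondrial ribosomal RNA genes took 0.932 ± 0.0264% and 0.439 ± 0.0104%, a share that also depends on how polyadenylated RNA was selected.

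Cholesterol efflux and LXR target genes had no common direction: 7 of 20 rose, 8 fell and 5 did not pass (9 and 9 adjusted over the list alone). Median (-0.15) and mean (-0.04) were negative while the test pointed up (adjusted p = 0.928), and the median was 0.05 on TPM and 0.04 under quantile normalisation. NPC1, which exports cholesterol from lysosomes, rose by 0.81, and the desaturase SCD fell by 0.64. The exporter ABCG1 had a log2 change of 0.13 (adjusted p = 0.0687). It passed as higher in 16 of 29 alternative settings, among them without siMCT4 replicate 3 (adjusted p = 0.0415), GC correction (adjusted p = 0.0369) and TPM (0.32, adjusted p = 0.00133), with 0.000869 to 0.383 over all of them. NR1H3, which encodes LXR alpha, had one of -0.25 (adjusted p = 0.0228), a call lost in 16 of 28 alternative settings. These include the fits without control replicate 1, 2 or 3 (adjusted p = 0.0518, 0.0866 and 0.0663) or siMCT4 replicate 1 (adjusted p = 0.0579) and TPM (-0.06, adjusted p = 0.516), the range for NR1H3 being 0.00174 to 0.563. Sterol synthesis genes fell, with 0 higher, 15 lower and 8 not passing of 23 (0 and 15 adjusted over the list alone, median -0.50, adjusted p = 6.81e-06, or adjusted p = 0.0417 with an estimated correlation). SQLE, squalene epoxidase, fell from 1334 ± 40.4 to 594 ± 58.2 CPM, and DHCR7 and MSMO1 fell by 1.85 and 1.10.

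Receptors of modified LDL moved apart, with 2 of 14 higher, 9 lower and 3 not passing (2 and 9 adjusted over the list alone, median -0.48, adjusted p = 0.0254). The call was lost in 15 of 31 alternative settings. Among these were an estimated correlation (adjusted p = 0.283) and the fits without siMCT4 replicate 1, 2 or 3 (adjusted p = 0.0672, 0.0669 and 0.0858). Over camera's alternatives the adjusted p of the list ran from 0.00101 to 0.559. The scavenger receptor CD36 fell from 816 ± 6.21 to 413 ± 14.2 CPM, LRP1 by 1.11 (by 0.58 after GC and length correction) and TLR2 by 0.91. MSR1 had a log2 change of -0.24 (adjusted p = 0.00935). The call of MSR1 was lost in 12 of 29 alternative settings, among them without siMCT4 replicate 1 (adjusted p = 0.0584), siMCT4 library 3 alone (adjusted p = 0.113) and TPM (-0.04, adjusted p = 0.538), with 0.00131 to 0.538 over all of them. OLR1, the lectin-like ox-LDL receptor, rose from 7.90 ± 0.368 to 66.3 ± 2.91 CPM. The median was the same, at -0.48, with MARCO at its bound. PPAR targets and fatty acid oxidation were not called (4 of 18 higher, 7 lower, 7 not passing, or 4 and 7 adjusted over the list alone, median -0.14, and 0.03 on TPM; adjusted p = 0.288). The receptor gene PPARG rose by 1.248 and the lipid droplet protein gene PLIN2 fell by 1.18.

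Apoptotic cell clearance was not called (7 of 25 higher, 10 lower, 8 not passing, or 7 and 11 adjusted over the list alone, adjusted p = 0.5). Its median was -0.16 with the test pointing down, its mean 0.10, and its median 0.13 on TPM and 0.04 on FPKM. The mean includes THBS1 (log2 change 7.39), which was uneven within siMCT4. THBS1 had 6, 3 and 0 counts in controls and 809, 786 and 12 in siMCT4 libraries 1, 2 and 3. The engulfment receptor MERTK rose by 0.86, and UCP2 and CD36 fell by 1.14 and 0.98. Lysosomal genes were as often higher as lower (13 and 14 of 33, 6 not passing, or 13 and 14 adjusted over the list alone, median -0.07, adjusted p = 0.889), with the median at 0.13 on TPM, 0.03 on FPKM and 0.00045 under quantile normalisation. The protease CTSH fell by 0.66.

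Integrated stress response genes fell, with 2 of 23 higher, 16 lower and 5 not passing (3 and 17 adjusted over the list alone, median -0.72, adjusted p = 1.31e-08, or adjusted p = 0.0226 with an estimated correlation). Examples are asparagine synthetase ASNS (log2 change -1.16), the serine synthesis genes PSAT1 (-0.90) and PHGDH (-1.57), the transporter SLC7A5 (-2.10) and the lipoprotein receptor VLDLR (-1.52). The unfolded protein response was not called (6 of 23 higher, 8 lower, 9 not passing, or 6 and 8 adjusted over the list alone, adjusted p = 0.521). Its median was -0.08, and 0.12 on TPM and 0.02 on FPKM; the chaperones CANX and HSP90B1 fell by 0.46 and 0.48. NRF2 targets were not called (4 of 23 higher, 6 lower, 13 not passing, or 4 and 7 adjusted over the list alone, adjusted p = 0.304); the median was 0.05 and the mean -0.04, the test pointed down, and the median was -0.01 with GC and length corrected. The untested member AKR1B10 had 0 counts in controls and 593, 519 and 0 in siMCT4 libraries 1, 2 and 3. Malic enzyme ME1 and ferritin heavy chain FTH1 fell by 1.64 and 1.08.

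Hypoxia response genes were 7 higher, 12 lower and 5 not passing of 24 (8 and 12 adjusted over the list alone, median -0.28, adjusted p = 0.0389, or adjusted p = 0.269 with an estimated correlation). EPAS1, which encodes HIF-2 alpha, fell by 1.59, VLDLR by 1.52 and NDRG1 by 0.75, and LOX, a collagen-crosslinking oxidase, rose by 2.11. The list lost its call in 17 of 31 alternative settings. Among these were the fit without control replicate 1 (adjusted p = 0.0572), log2(FPKM + 1) (adjusted p = 0.163) and siMCT4 library 3 alone. The range over camera's alternatives was 0.0111 to 0.305. Histone acylation writers, erasers and readers were not called (5 of 25 higher, 6 lower, 14 not passing, or 5 and 6 adjusted over the list alone, median -0.02, adjusted p = 0.879). The median was 0.09 on TPM and 0.10 after GC correction. The acyltransferase EP300 rose by 0.60 (adjusted p = 0.00016), from 189 ± 13.5 to 288 ± 3.74 CPM, and the acetyl-CoA synthetase ACSS2 fell by 0.92.

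Matrix genes were 10 higher, 8 lower and 9 not passing of 27 (11 and 10 adjusted over the list alone, median 0.15, adjusted p = 0.0054, or adjusted p = 0.0975 with an estimated correlation). Fibronectin, FN1, rose from 196 ± 15.1 to 2534 ± 84.9 CPM, and MMP12 and MMP7 rose by 7.26 and 2.12, while MMP9 and the inhibitor TIMP2 fell by 1.72 and 0.91. The list lost its call in 17 of 31 alternative settings. Among these were log2(FPKM + 1) (adjusted p = 0.438), edgeR without a filter (adjusted p = 0.238), camera on ranks (adjusted p = 0.499) and siMCT4 library 3 alone. Over camera's alternatives its adjusted p ran from 0.000169 to 0.538. The member THBS1 (log2 change 7.39) had 6, 3 and 0 counts in controls and 809, 786 and 12 in siMCT4 libraries 1, 2 and 3.

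Ribosomal protein genes fell in 36 of 36 cases, with 0 higher and 0 not passing (0 and 36 adjusted over the list alone, median -0.85, adjusted p = 1.76e-13, or adjusted p = 0.306 with an estimated correlation). RPL3 fell by 1.29, RPS2 by 1.11, RPL15 by 0.87 and RPL4 by 0.78, and the medians of siMCT4 libraries 1, 2 and 3 were -0.73, -0.68 and -1.12. Cell cycle genes were 2 higher, 27 lower and 5 not passing of 34 (2 and 28 adjusted over the list alone, median -1.65, adjusted p = 1.76e-13, or adjusted p = 0.235 with an estimated correlation). The mitotic checkpoint kinases BUB1B and BUB1 fell by 3.40 and 2.34, cyclin A2, CCNA2, by 2.49 and NUSAP1 by 1.96; library medians were -1.53, -1.64 and -2.23. Replication-dependent histone genes, normally transcribed in S phase without a polyA tail, moved the other way: 10 of 11 rose, 0 fell and 1 did not pass (10 and 0 adjusted over the list alone, median 1.16, adjusted p = 0.000973, or adjusted p = 0.0761 with an estimated correlation). H2BC4, H2BC5, H2BC21 and H2BC12 rose by 2.93, 2.28, 1.16 and 1.01, and H2BC12 by 1.72 after GC and length correction.

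**Figure D4:**
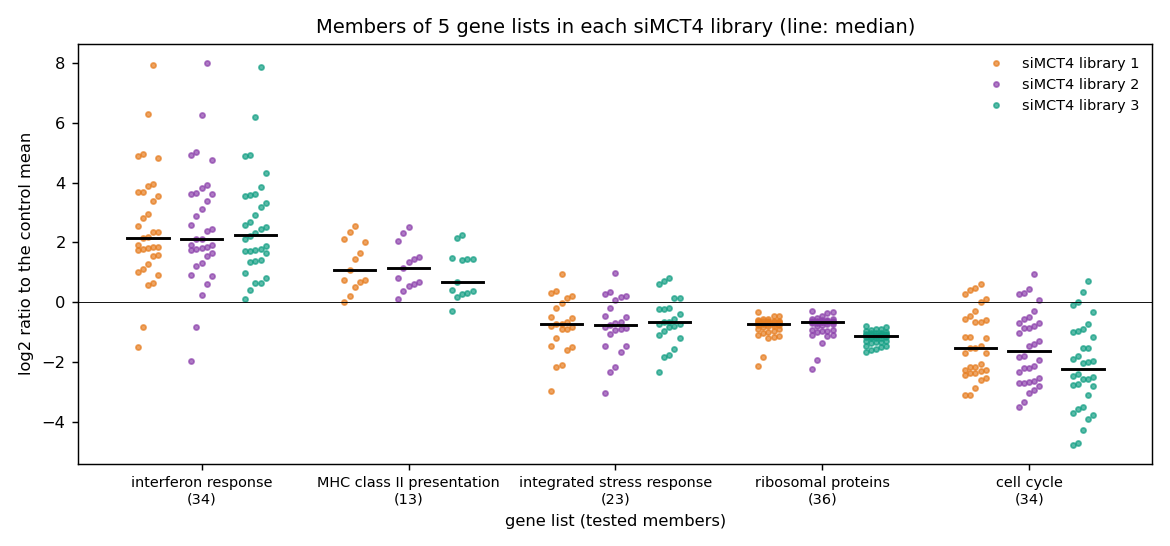
Log2 ratio to the control mean (y axis) of every tested member of 5 gene lists (x axis) in siMCT4 libraries 1, 2 and 3; each point is a gene and each black bar a median. Interferon and MHC class II genes lie mostly above 0 and the other lists mostly below 0 in every siMCT4 library, with cell cycle medians of -1.53, -1.64 and -2.23.

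The p53 target list was not called (9 of 25 higher, 6 lower, 10 not passing, or 10 and 7 adjusted over the list alone, median 0.20, adjusted p = 0.252). The pro-apoptotic BCL2L11 and the cyclin-dependent kinase inhibitor CDKN1A rose by 1.91 and 1.22, and the death receptor TNFRSF10B fell by 0.83. Immediate early and heat shock genes were not called (10 of 28 higher, 6 lower, 12 not passing, or 11 and 6 adjusted over the list alone, median 0.04, adjusted p = 0.073), but passed as higher with siMCT4 library 3 alone (adjusted p = 0.00155) and after GC correction (adjusted p = 0.0401), the range over camera's alternatives being 0.00155 to 0.856. The nuclear receptor NR4A3 rose by 1.91 and the chaperone HSPH1 by 1.05.

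Monocyte-to-macrophage differentiation genes fell: 0 of 25 were higher, 16 lower and 9 not passing (1 and 17 adjusted over the list alone, median -0.39, adjusted p = 3.1e-06, or adjusted p = 0.0468 with an estimated correlation). The Fc receptor FCGR1A fell by 1.66, the tetraspanin CD9 by 2.32, CD4 by 0.68, and CSF1R, the receptor of macrophage colony-stimulating factor, from 1729 ± 40.7 to 946 ± 54.0 CPM. The leukaemia progenitor list also fell, with 1 of 13 higher, 5 lower and 7 not passing (1 and 5 adjusted over the list alone, median -0.47, adjusted p = 0.0211, or adjusted p = 0.335 with an estimated correlation). The progenitor transcription factor MYB and the receptor FLT3 fell by 1.99 and 2.27 and CTSG by 0.43 (not called without control replicate 3, adjusted p = 0.0514, with 0.00152 to 0.0832 over all alternatives), and the granulocytic factor CEBPE rose by 3.78 (4.38 without control replicate 3 and 3.04 without siMCT4 replicate 3), a call lost on FPKM without a filter (adjusted p = 0.0672, with 1.8e-08 to 0.0672 over all alternatives); the list was not called with siMCT4 library 3 alone (adjusted p = 0.0763, with 0.000282 to 0.335 over camera's alternatives).

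Lists of other cell types were also tested. Endothelial markers were 0 higher, 3 lower and 6 not passing of 9 (0 and 3 adjusted over the list alone, median -0.65, adjusted p = 0.00172, or adjusted p = 0.0833 with an estimated correlation), with VWF, PECAM1 (log2 change -0.65) and TIE1 (-0.48, and -0.20 after GC correction) lower. EGFL7, with a GC content of 68.1%, had 2499, 2398 and 2548 counts in controls and 427, 297 and 1826 in siMCT4 libraries 1, 2 and 3 (adjusted p = 0.0617). It passed as lower in 17 of 28 alternative settings, among them without siMCT4 replicate 3 (adjusted p = 7.88e-06, with 7.88e-06 to 0.171 over all of them). Fibroblast and smooth muscle markers were not called (3 of 8 higher, 0 lower, 5 not passing, or 2 and 0 adjusted over the list alone, adjusted p = 0.716); the median was 0.25, but -0.06 on FPKM, -0.13 with median-ratio scaling and -0.08 under quantile normalisation. Of the list's 13 members with values, 5 were not tested, among them the collagen COL1A2, with 0 counts in controls and 1892, 1782 and 0 in siMCT4 libraries 1, 2 and 3. The actin gene ACTA2 had 0, 0 and 4 counts in controls and 38, 28 and 67 in siMCT4 (adjusted p = 0.006), a log2 change of 4.85. Without control replicate 3 the controls had 0 counts, so the fitted log2 change of 8.45 is not a measured size. DES had a log2 change of 0.65 (adjusted p = 0.0285), 1.13 after GC correction, and ratios of 0.74, 0.82 and 0.36 in siMCT4 libraries 1, 2 and 3. Its call was lost in 6 of 27 alternative settings, among them without control replicate 1 or 2 (adjusted p = 0.0791 and 0.0862) or siMCT4 replicate 1 or 2 (adjusted p = 0.0775 and 0.085). With siMCT4 library 3 alone against the controls the log2 change of DES was 0.37, and this was among the settings without a call. The lowest adjusted p of DES over all alternatives was 0.000337, from limma on FPKM with array weights. Lymphocyte markers were not called (1 of 7 higher, 2 lower, 4 not passing, or 1 and 2 adjusted over the list alone, adjusted p = 0.616); median (0.10) and mean (0.32) were positive while the test pointed down, and the median was -0.43 on FPKM, -0.50 with median-ratio scaling, -0.35 on TPM and -0.47 under quantile normalisation. TRAC fell by 2.55 and CD79A rose by 2.90. Only 2 epithelial markers could be tested, too few for a list test (1 higher, 0 lower, 1 not passing, or 1 and 1 adjusted over the list alone, median 0.56), and KRT8 had 13, 9 and 14 counts in controls against 122, 56 and 13 in siMCT4 libraries 1, 2 and 3 (adjusted p = 0.0453). The call of KRT8 was lost in 9 of 15 alternative settings, among them without control replicate 1, 2 or 3 (adjusted p = 0.118, 0.135 and 0.111) or siMCT4 replicate 1 or 2 (adjusted p = 0.175 and 0.0766), with 0.00141 to 0.999 over all of them.

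The functional terms attached to genes in the deposited table were tested too, and those named here were chosen after their values were seen. Of 4062 terms tested, 113 were called up and 187 down. CCR chemokine receptor binding had 14 of 20 genes higher and 3 lower (median 4.36, adjusted p = 2.28e-44, or adjusted p = 0.422 with an estimated correlation). Negative regulation of viral genome replication had 27 of 41 higher and 0 lower (median 1.23, adjusted p = 1.26e-37, or adjusted p = 0.296 with an estimated correlation). Cytoplasmic translation had 0 of 87 higher and 78 lower (median -0.81, adjusted p = 2.41e-15, or adjusted p = 0.682 with an estimated correlation). Formation of COPII vesicle, a step of transport from the endoplasmic reticulum, had 12 of 16 higher and 0 lower (median 0.55, adjusted p = 4.97e-06, or adjusted p = 0.624 with an estimated correlation). With an estimated correlation 0 terms passed camera's adjusted p, while 289 had an unadjusted p under 0.05 and the directional test of fry, which does not compare a term with other genes, called 2771.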

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

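The settings chosen only after the results were seen were the GC corrections, genes under 55% GC, siMCT4 library 3 alone, halved counts, robust edgeR and the lactate list without SLC16A3; the others were planned. SLC16A3 stayed lower and past the threshold in every setting in which it was tested, and lay between -3.28 and -3.12 with each library left out. SLC16A3 has a GC content of 62.6%, and its log2 change was smaller after GC correction (-2.78) and after GC and length correction (-2.75). On log2(FPKM + 1) it was -2.37. The named genes kept direction and side of the threshold in 3486 of 3621 comparisons with an alternative, 73 being weaker, 49 stronger and 13 reversed. For lists the numbers were 841 of 989, 94, 15 and 39. Most named genes were chosen for a large change or a small adjusted p in these same data, so their count does not stand for all called genes. The interferon, NF-kB, stress response, sterol and differentiation lists lost their call in none of the settings. Leaving out 1 library gave 3409 to 4894 genes higher, 3160 to 4814 lower, 19 to 20 lists and 299 to 347 terms; the gene ranges run from without control replicate 2 to without siMCT4 replicate 3. With the replicate block edgeR called 3341 genes higher and 3580 lower, 19 lists (hypoxia lost, adjusted p = 0.0734) and 294 terms, with DES and KRT8 losing and EGFL7 gaining a call among the named genes; limma on FPKM with the block called 2494 genes lower and 123 terms. Libraries with the same number did not deviate together (r = -0.0616, -0.00295 and -0.0547 across genes, which are not independent replicates). Of the 8260 calls, 7480 (90.6%) were kept in the same direction after GC correction and 7311 (88.5%) after GC and length correction. With siMCT4 library 3 alone, a lone library assumed to vary like the controls, 5955 of 8248 calls were kept (72.2%) and 506 terms were called. Without SLC16A3 the lactate list stayed called at the preset correlation (adjusted p = 0.0019) and not at an estimated one (adjusted p = 0.0831). IL6 was too low to test, and which other changes a greater depth would reach was not tested.

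Counts moved by over 1.5 times as follows, and except where thresholds or filters were stricter by construction the cause was not tested. A 2-fold minimum left 1268 genes higher and 1339 lower, and an adjusted p under 0.01 left 2725 and 2745. Genes lower numbered 2350 on TPM; a mean FPKM of at least 5 left 2295 higher, 1630 lower, 11 lists and 106 terms. Lists called were 13 under quantile normalisation, 13 with array weights and 7 with an estimated correlation. Terms called were 668 without a filter, 125 on log2(FPKM + 1), also without trend and with robust fitting, 140 with median-ratio scaling, 119 on TPM, 116 under quantile normalisation, 122 with pseudocounts of 0.1 and 0.5, 704 on FPKM without a filter, 0 with an estimated correlation and 2771 with fry.

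Directions turned in the following results, for untested reasons. The log2 change of ABCA1 was 0.0447 on log2(FPKM + 1), with FPKM filters of 0.1, none or a mean of 5, without trend, with robust fitting and with the replicate block. It was 0.0449 and 0.0451 with pseudocounts of 0.5 and 0.1, 0.0462 with array weights, 0.137 on TPM and 0.130 under quantile normalisation, where MT-ATP6 was at 0.0838 (adjusted p = 0.047). Of the genes named outside the rule, IFI6 turned in 5 of 28 settings and IRF7 in 1, siMCT4 library 3 alone, as the report gives. None of the turned lists was called in the setting that turned it. Over camera's alternatives their adjusted p ran from 0.192 to 1 for cholesterol efflux, 0.252 to 1 for lysosome, 0.543 to 1 for histone acylation, 0.136 to 1 for NRF2, 0.422 to 0.951 for apoptotic clearance and 0.442 to 0.997 for lymphocyte markers. The cholesterol efflux list pointed down at adjusted p = 0.974 in edgeR without a filter, 0.979, 0.783 and 0.908 without control replicate 1, 2 or 3, 0.958 on TPM, 0.995 with a pseudocount of 0.1, 1 with the FPKM block and 0.947 on ranks. The lysosome list ran from 0.765 to 0.964 with 1 library left out and pointed up at 0.964 and 0.951 without siMCT4 replicate 1 or 3, 0.991 on FPKM, without trend and with robust fitting, 0.958 on TPM, 0.796 under quantile normalisation, 0.884 and 0.725 with FPKM filters of 0.1 and none, 0.999 with array weights, 1 with the FPKM block and 0.81 with GC correction. The histone acylation list pointed up at 0.991 on FPKM, without trend and with robust fitting, 0.858 on TPM, 0.995 and 0.999 with pseudocounts of 0.1 and 0.5, 0.699 and 0.543 with FPKM filters of 0.1 and none, and 0.999 with array weights. The NRF2 list ran from 0.302 to 0.748 with 1 library left out and pointed up at 0.748 without siMCT4 replicate 3, 0.958 on TPM, 0.785 under quantile normalisation, 0.884 and 0.725 with FPKM filters of 0.1 and none, 0.824 with array weights and 1 with the FPKM block. Apoptotic clearance ran from 0.565 to 0.951 with 1 library left out and pointed up at 0.951 without siMCT4 replicate 3 and 0.614 with genes under 55% GC, and lymphocyte markers at 0.997 on ranks.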

Other observations

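Of the tests in this part, those of the 3 patterns were chosen after the result was seen, except the loss of fragments in GC-rich genes of low abundance and the ribosomal protein pseudogenes; the splits of the libraries were planned, and the genes named here were chosen after their values were seen. The annotated term tryptophan metabolism was not called (9 of 32 genes higher and 11 lower, median -0.16, camera adjusted p = 0.473; adjusted p = 0.889 with an estimated correlation), so the changes that follow are of single genes. TDO2, tryptophan dioxygenase, rose from 346 ± 4.03 to 1089 ± 32.5 CPM, KYNU and KMO, which act further along the kynurenine pathway, by 1.33 and 1.28 on the log2 scale, and IL4I1, a secreted amino acid oxidase, from 69.5 ± 1.59 to 365 ± 7.60 CPM (n = 3 libraries per group). AFMID, the formamidase of the same pathway, fell by 1.71 and the arginine synthesis gene ASS1 by 1.92. The amino acid transporter SLC7A8 rose by 2.99, the water and glycerol channel AQP9 by 2.52 and the aminopeptidase ANPEP from 1079 ± 37.1 to 5127 ± 128 CPM. ALDH1A2, which makes retinoic acid, rose from 16.4 ± 1.41 to 283 ± 4.38 CPM. The highest adjusted p among these genes in edgeR's quasi-likelihood test was that of KMO (adjusted p = 3.24e-05), and with siMCT4 library 3 alone KMO had a log2 change of 1.36 (adjusted p = 0.000247).

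The term integrin complex had 3 of 24 genes higher and 10 lower (median -0.05, camera adjusted p = 0.0421; adjusted p = 0.659 with an estimated correlation). The fibronectin receptor subunit ITGA5 rose from 745 ± 40.9 to 2451 ± 61.9 CPM beside FN1, while the laminin receptor subunits ITGA3 and ITGA6 fell by 1.91 and 1.85 on the log2 scale and the common partner ITGB1 by 1.27. The leukocyte integrin ITGAL fell by 1.898 and ITGB2 by 1.32. The term laminin binding had 2 of 19 genes higher and 10 lower (median -0.36, camera adjusted p = 0.000519; adjusted p = 0.624 with an estimated correlation), and receptor-mediated endocytosis 9 of 66 higher and 34 lower (median -0.24, adjusted p = 0.000357; adjusted p = 0.624 with an estimated correlation). Among other single genes, the T cell ligand CD274 rose by 1.72, PDCD1LG2 by 2.03 and CD276 by 1.59 on the log2 scale, the highest of the adjusted p values being that of CD276 (2.20e-05).

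The rise of the interferon list raises the question whether it came from MCT4 loss or from the siRNA. Its median was 2.21 after GC and length correction, against 2.09 without, and its lowest median in a siMCT4 library was 2.12, which argues against sequence composition or a single odd library as the whole cause. Interferon beta, IFNB1, had 67 counts over the siMCT4 libraries and 0 over the controls (adjusted p = 0.00265), and the sensors of double-stranded RNA TLR3 and IFIH1, themselves induced by interferon, rose by 4.28 and 2.17 on the log2 scale. A response to siRNA and an effect of MCT4 deficiency both predict these values and cannot be told apart, because siRNA and MCT4 loss go together in the siMCT4 libraries and the labels do not say whether the controls received a non-targeting siRNA. A candidate explanation that stays open is therefore that part of the interferon rise is a reaction to the siRNA.

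The siMCT4 libraries 1 and 2 stood apart from library 3 on principal component 2 (13.8% of variance). They also stood apart in chi-squared per degree of freedom over genes, computed on halved counts. It was 4.86 between libraries 1 and 2, 29.6 and 34.2 between each of them and library 3, and 6.71 to 9.48 between controls. Among 194 GC-rich genes of low abundance, libraries 1 and 2 lay -0.688 from library 3 on the log2 scale, against 0.0624 for genes under 50% GC, as a GC-dependent loss of fragments in those libraries would give. An effect of MCT4 loss that differed between the libraries was not tested. In addition 83 genes had at least 20 counts in libraries 1 and 2 each and at most 6 over the other 4 libraries, among them IGFBP5 (2423 and 1926), COL1A2 (1892 and 1782) and MTAP, with 86 counts over both and 0 elsewhere, where another pair of libraries had at most 4 such genes. This could come from a trace of RNA of other human cells. MTAP is a neighbour of CDKN2A, which THP-1 is known to lack. Since MTAP is among the genes chosen for this pattern, its counts are no separate test of that explanation. The 83 genes sum to 0.0255% and 0.0209% of counts, and THBS1 (809 and 786 counts against 12 in library 3) may share their source. However, the collagen COL1A1 was not raised (2.85 and 2.52 CPM against 4.43 to 6.32 CPM in controls).

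All 36 tested ribosomal protein genes fell, and technical causes were weighed. The median was -0.876 after GC correction, against -0.85, which argues against GC content as the cause. A loss of short transcripts would lower other short, abundant genes too, but 170 such genes matched for length and GC content had a median of -0.0534 with quartiles of -0.418 and 0.184, against -1.08 and -0.763 for the ribosomal protein genes; the matching was first done on the longest and then on the principal transcript, whose median length was 1247 bases against 933. Reads moved to processed pseudogenes would raise these, but 189 pseudogenes had a median of -0.686, with 67 lower and 6 higher. Lower ribosomal protein transcript levels in MCT4-deficient cells therefore stay a hypothesis, beside an untested effect of the siRNA itself, and may be examined with another siRNA.

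The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 8260 genes, 20 lists and 300 terms, and the highest of the other splits gave 1 gene, 12 lists and 199 terms. Every other split mixes control and siMCT4 libraries, so their difference adds to the spread within its groups. The low gene count of those splits therefore says nothing about chance. They also hold unequal numbers of siMCT4 libraries on each side, so their list and term calls are no measure of chance either.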
